A study of Mus musculus with 26 samples.

How the data were processed

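Polyadenylated RNA was made with dUTP strand marking, per the labels' protocols, into 10 libraries of cultured pro-B cells in 4 groups. The other 16 samples of the series, of chromatin accessibility and protein binding, were not analysed here. Groups were taken from the sample titles. CASAVA, RSEM and DESeq are the tools that the submitters' processing notes name for these samples, with no versions and with the mm10 genome build.

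The mean columns hold a signal in normalized reads, a mean per group of reads divided by library size factors by the authors, which fits the file headers and the values. The log2 fold change is that of the Brg1-depleted over the control mean, per the file headers. The p-value and the Benjamini-Hochberg adjusted p-value are the authors' own, per the file headers, with p-values of 0.0001 and above rounded to 4 decimals. The deposited linear fold and the exon length were read as well. The adjusted values imply about 23788 genes in the adjustment for deletion and 24336 for knockdown, more than are listed, and no listed mean is 0. Genes without reads in 1 group may therefore be missing from the tables, which was not tested. The authors also mark 9145 genes of the deletion table and 9332 of the knockdown table as confounded, a mark that no source used here defines.

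The tests were fixed before the data were examined. Because the tables hold no values per sample, the calls are those of the authors' deposited tables at an adjusted p under 0.05, with no test of differences between experiments. The planned count models were not run. Agreement was measured by Pearson and Spearman correlations over genes, by the overlap of calls against that of independent lists and by Fisher's exact test. The 33 gene lists were fixed in advance, as were the named genes. These were Smarca4, the 10 largest called rises and falls per experiment among genes above the median level (leaving out predicted genes, Riken clones and antigen receptor segments), up to 10 genes per direction called in both, and up to 4 genes per list by adjusted p. List members were matched by symbol or gene identifier. A list was said to stand apart when its median lay outside the 2.5 to 97.5 percentiles of 10000 random lists with the same size, drawn from 20 bins of mean level. This describes the tables and is not a test over replicates.

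Each mean of the deletion table is a sum of whole reads from 2 libraries, each worth a fixed step. The steps were found from the lowest values and refined by least squares. Within a tolerance of 6.0e-05, all 19404 genes had a whole-read solution in both groups, 100% of the values, where 2.25% of random values up to 100 had one. In 18352 genes, 94.6%, the solution was the only one, and for the library totals the most balanced solution was taken in the others. Size factors computed anew from these reads by the median of ratios differed from the steps by at most 0.0614%. In the knockdown table, which pools 3 libraries, the steps gave the depths alone. The libraries of a group differed far beyond sampling noise, with a chi-square per gene of 18.3 for controls and 24.3 for the Brg1-deleted group, so each counts as a separate library. The recovered libraries carry no replicate number and are named by depth.

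As additions chosen after the data were examined, limma 3.58.1 in R 4.3.3 was run with a mean-variance trend on log2 of recovered reads plus 0.5 over the size factor, for genes with a mean of at least 1 and 1 solution, and camera on the same values with a preset correlation of 0.01 or an estimated one. Only list members with 1 solution entered camera, which leaves out the most abundant genes. Other alternatives were a mean of at least 10 CPM, a 1.5-fold minimum, an adjusted p of 0.1, an adjustment over listed genes, protein-coding genes alone and genes without the confounded mark. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest.

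The read recovery and the limma step were tested on simulated data. For the deletion comparison, every one of the 17018 simulated genes with 1 solution was resolved right (100%). In the limma step on 16110 simulated genes without pairing, 39.2% of 74 genes changed 4-fold and 0 of 90 changed 2-fold were called. With matched libraries the shares were 97.3% and 67.8%, with 5 false calls. The simulation planted a shared effect in these pairs and the fit was given them. It therefore does not measure false calls where the pairs are chosen by similarity. From the real deletion values of genes at or above the median level, 400 lists of 20 genes were drawn at random. Of these, 5.0% fell outside the central 95%, which such draws give by construction. When shifted by 0.5, 95.3% of these lists were found. This share does not hold for lists of lower level, such as mast cell markers, whose random range was wider, from -0.44 to 0.55.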

Results

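RNA-seq of cultured mouse pro-B cells was used to ask how gene expression depends on Brg1, the ATPase subunit of the SWI/SNF chromatin remodelling complexes, which is encoded by Smarca4. B220+ bone marrow cells were grown with IL7 and SCF for 7 days. In the deletion experiment, cells with wild-type Brg1 alleles (2 libraries) and cells with floxed Brg1 alleles (2 libraries), all carrying ER-Cre, received 0.3 µM tamoxifen for the last 60 hours. In the knockdown experiment, Rag1-null cells, which cannot rearrange antigen receptor genes, were infected on days 3 and 4 with retrovirus carrying a control shRNA (3 libraries) or a Brg1 shRNA (3 libraries) and enriched for infected cells. Each experiment has its own table, with 1 mean per group and gene, and these are printed as the authors' means. The tables listed 19404 genes for deletion and 19719 for knockdown. The values of the deletion table could be resolved into whole reads per library, which came to about 10759433 and 10221353 reads in the control libraries and 11591427 and 8781120 in the Brg1-deleted libraries. In the knockdown experiment, the control libraries held about 10509284, 9421325 and 5201372 reads and the Brg1 shRNA libraries about 11050878, 9837722 and 8304423. No source used here says that the libraries of a group came from separate mice. The p-values therefore measure only the spread between libraries, which may not be that between mice.

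Smarca4 (ENSMUSG00000032187, mm10 chromosome 9, 21616169 to 21704230) was lower in both Brg1-depleted groups. After deletion its authors' mean was 6067 against 17898 in controls, a 2.95-fold fall with an adjusted p of 0.0008 in the authors' deposited table. After knockdown the authors' means were 6743 and 13340, and the authors' deposited table gives a 1.98-fold fall with an adjusted p of 0.0472. Reads from a deleted allele outside the removed exons can still count towards this gene. The Smarca4 means are too high to be resolved into 1 whole-read value per library.

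Deletion of Brg1 in cultured pro-B cells changed 286 genes in the authors' deposited table at an adjusted p threshold of 0.05, of which 142 were higher and 144 lower. The fall was deepest, among called genes above the median level, for Col5a3, a fibrillar collagen gene (chromosome 9, 20770050 to 20815067), from an authors' mean of 384 to 1.16, and this gene lies 0.801 Mb from Smarca4. H19, an imprinted noncoding RNA, went from 188 to 3.92, Pcdh9, a protocadherin, from 231 to 12.9, and Crhbp, the binding protein of corticotropin-releasing hormone (chromosome 13, 95431371 to 95444831), from 1675 to 134. Among the rises, Islr2 (chromosome 9, 58196298 to 58204319) went from an authors' mean of 25.8 to 343, Egfl6 (chromosome X, 166523007 to 166585720) from 47.8 to 533 and Srpk3 (chromosome X, 73774405 to 73778925) from 68.3 to 703.

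The other large rises were in Sorbs2, 9.65-fold, Pdlim2, 6.81-fold, Rpl10-ps1, 5.18-fold, Rhobtb2, 5.17-fold, Dnah1, 5.07-fold, Bcl6, 4.95-fold, and Ccdc157, 4.93-fold, all past the adjusted threshold in the authors' deposited table. Bcl6 is a transcriptional repressor of B cells, and its adjusted p there was 4.97e-06. Rpl10-ps1 is named as a ribosomal protein pseudogene, and reads shared with near-identical copies make its value uncertain. The other large falls in the authors' deposited table were in Gldc, 10.7-fold, the neuronal tubulin gene Tubb3, 9.34-fold, Ly6c2, 7.54-fold, Elane, 6.93-fold, the deubiquitinase gene Uchl1, 6.77-fold, and Thy1, 6.30-fold. Gldc, which encodes glycine decarboxylase, had an adjusted p of 0.045 in the authors' deposited table. Of the 286 called genes, 244 could be resolved into whole reads per library. The groups did not overlap in any of these 244, but they were called from the same libraries, so their separation is no independent check. Of all 16774 resolved genes with a mean of at least 1, called or not, 48.1% were separated in this way, where chance gives 33.3% for 2 libraries against 2.

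**Figure D1:**
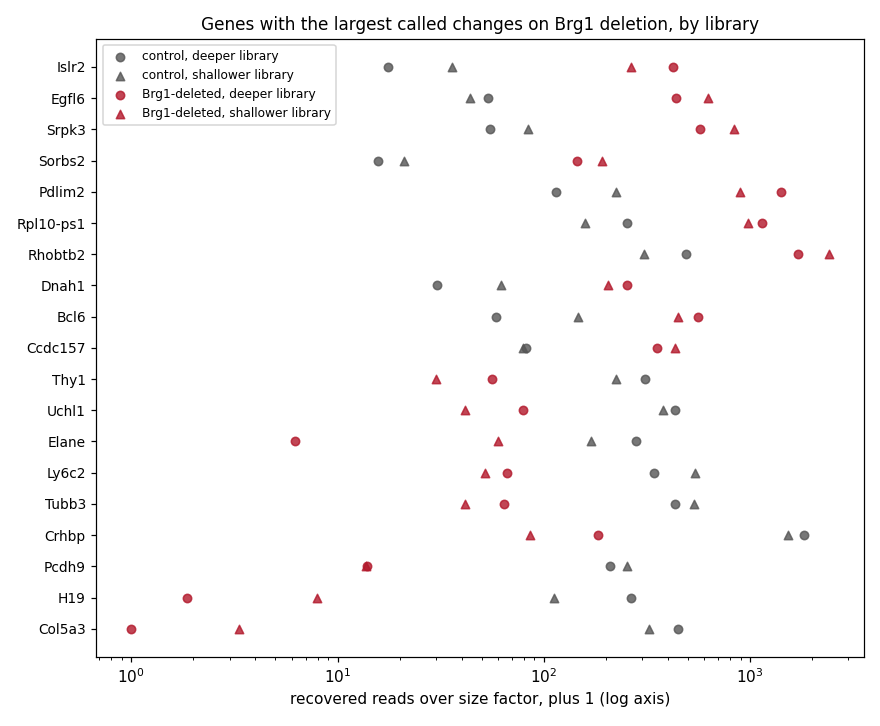
Recovered reads divided by the library's size factor, plus 1, on a log axis, for the named genes with the largest called changes on Brg1 deletion, except Gldc, which could not be resolved. Circles are the deeper and triangles the shallower library of each group, grey for control and red for Brg1-deleted. No red point lies between the grey points of its gene, and Col5a3 lies at 447 and 322 in the controls against 0 and 2.33 in the Brg1-deleted libraries before 1 is added.

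Among the fixed lists, ribosome biogenesis, the making of ribosomes in the nucleolus, held the most called falls. All 30 listed members were below 0 on deletion, with a median log2 fold change of -1.17, against -0.26 to 0.18 for the central 95% of random lists of like level. Called falls numbered 10, among them Rrp1b, Ncl, Gnl3 and Nolc1, and 24 falls passed when adjusted over the list alone. Ncl, the nucleolar protein nucleolin, went from an authors' mean of 17309 to 6580, with an adjusted p of 0.0056 in the authors' deposited table. Gnl3, nucleostemin, went from 1379 to 508, with an adjusted p of 0.0083 in the authors' deposited table. Translation factors and tRNA synthetases had a median of -0.84, with 1 called fall of 30, in Eif5a, and 10 falls adjusted over the list alone. Cytosolic ribosomal proteins had a median of -0.24, at the 4.69 percentile of random lists, and none of the 30 was called, with 1 passing when adjusted over the list alone. Its 9 resolved members had medians of -0.54 and -0.29 in 2 matched pairs, each a control and a Brg1-deleted library joined by similarity. An added camera test on the recovered reads gave an adjusted p = 0.726 with an estimated correlation for each of these 3 lists. With the preset correlation of 0.01, which takes the genes of a list as nearly independent, the adjusted p was 4.67e-14 for ribosome biogenesis. It was 1.57e-08 for translation factors and tRNA synthetases and 0.0156 for cytosolic ribosomal proteins.

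Lists of energy metabolism and nucleotide supply had medians below the random range, with few called members. Glycolysis had a median of -0.98 and 4 called falls of 20, in Pgam1, Eno1, Tpi1 and Ldha, with 9 falls adjusted over the list alone. Eno1, the enolase gene, went from an authors' mean of 5533 to 1655, and Pgam1, phosphoglycerate mutase, from 1016 to 282, both with an adjusted p of 0.0003 in the authors' deposited table. Oxidative phosphorylation had a median of -0.42 and 1 called fall of 25, in Cycs, the cytochrome c gene, and 1 passed when adjusted over the list alone. Nucleotide and one-carbon synthesis had a median of -0.94 with all 24 members below 0. None of these 24 was called over all genes, and 15 falls passed when adjusted over the list alone, with Gart at an adjusted p of 0.0578 in the authors' deposited table. In camera the 3 lists each had an adjusted p = 0.726 with an estimated correlation. With the preset correlation it was 2.67e-05 for glycolysis, 2.67e-05 for oxidative phosphorylation and 2.17e-10 for nucleotide and one-carbon synthesis.

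Cell cycle lists were also below the random range. The G1/S and DNA replication list had a median of -0.65 and the G2/M and mitosis list a median of -0.36, with no call among 25 members of each and none adjusted over the list alone. Among the resolved members, the G2/M median was -0.18 in 1 matched pair and -0.61 in the other, and that of G1/S was -0.48 and -0.83. In the authors' deposited table Cdc6, a replication licensing factor, had a log2 fold change of -0.99 with an adjusted p of 0.1286. Genes of CDK inhibition and cell cycle exit lay on the other side, with a median of 0.74, 1 called rise of 16, in the antiproliferative gene Tob1, and 4 rises adjusted over the list alone. The 13 resolved members of that list had a median of 0.40 in the authors' deposited table, and of 0.48 and 0.33 in the matched pairs. Tob1 went from an authors' mean of 155 to 491 with an adjusted p of 0.0031 in the authors' deposited table. With an estimated correlation the adjusted p was 0.726 for each of the 3 lists. Camera with the preset correlation gave 1.60e-06 for G1/S and 0.0156 for both G2/M and CDK inhibitors.

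The unfolded protein and integrated stress response list had a median of -0.93, with 1 called fall of 20, in Hspa5, the chaperone of the endoplasmic reticulum, and 8 falls adjusted over the list alone. Its 13 resolved members had a median of -0.65 in the authors' deposited table, and of -0.53 and -0.56 in the matched pairs. Xbp1, a transcription factor of that response, had a log2 fold change of -1.30 and an adjusted p of 0.0505 in the authors' deposited table. The growth regulator Myc, a transcription factor, had authors' means of 1938 in controls and 517 after deletion, but its adjusted p of 0.146 in the authors' deposited table did not pass. Within the list of the Myc family and growth regulators, Mxd4, which encodes a partner of Max that opposes Myc, rose 3.33-fold in the authors' deposited table and Ncl fell, while the list median of 0.13 lay inside the random range and 5 genes passed when adjusted over the list alone. The 12 resolved members of the Myc list had medians of 0.65 and 0.35 in the matched pairs. The stress response list and the Myc list had an adjusted p = 0.726 with an estimated correlation. Camera with the preset correlation gave 0.0156 for the stress response list and 0.0967 for the Myc list.

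Lists of B cell genes had medians above 0. Pre-B cell receptor and B cell signalling genes had a median of 0.70, and 20 of 25 were above 0. Called rises were in Cd79b, a signalling chain of the B cell receptor, from an authors' mean of 8045 to 20542 with an adjusted p of 0.0106 in the authors' deposited table, and in Cd38, from 706 to 1958 with an adjusted p of 0.0038 in the authors' deposited table. When adjusted over the list alone, 3 genes passed, all higher. The surrogate light chain genes Igll1 and Vpreb1, picked out after their values were seen, lay on the other side of 0. In the authors' deposited table they had log2 fold changes of -0.27 and -0.63, and neither passed. B lineage transcription factors had a median of 0.36, with 1 called rise of 22, in Irf8, from 2730 to 6601 with an adjusted p of 0.0153 in the authors' deposited table, and 2 passed when adjusted over the list alone, 1 higher and 1 lower. Only 5 members could be resolved, with medians of 0.54 and 0.58 in the matched pairs. Ebf1, Pax5 and Ikzf1, which set up the B lineage and were picked out after their values were seen, had log2 fold changes of -0.02, 0.29 and 0.18 in the authors' deposited table, and none was called. In the V(D)J recombination and pre-B transition list, at a median of 0.26 (0.60 and 0.02 for resolved members in the matched pairs) inside the random range, Bcl6 was the called rise among 21 and 4 genes passed when adjusted over the list alone, 2 higher and 2 lower. With an estimated correlation the adjusted p was 0.726 for B cell signalling, 0.845 for B lineage transcription factors and 0.780 for V(D)J recombination. Camera with the preset correlation gave 0.0172, 0.360 and 0.458 in the same order.

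Of the myeloid markers, 22 of 24 lay below 0 after deletion. The list had a median of -0.58 and 4 called falls of 24, in the granule proteases Prtn3, Ctsg and Elane and in Ly6c2, with 6 adjusted over the list alone. Prtn3 went from an authors' mean of 443 to 81.4 with an adjusted p of 1.15e-06 in the authors' deposited table. The T cell and innate lymphoid list had a median of -0.58, with 15 of 22 members below 0 and 7 above. Called falls were 2, in the surface marker Thy1 and the kinase gene Lck, with 3 adjusted over the list alone. The median of this list was -0.12 in 1 matched pair and -0.72 in the other, and camera with a preset correlation gave an adjusted p of 0.212. The libraries of 1 group differed from each other in transcripts of other blood cells. The macrophage gene C1qb, chosen like S100a8 after its values were seen, stood at 11.7 and 210 in the 2 control libraries and at 9.30 and 117 in the 2 Brg1-deleted libraries, and the neutrophil gene S100a8 at 208 and 13.0 in controls and at 134 and 0.864 after deletion. With an estimated correlation the adjusted p was 0.726 for the myeloid and 0.845 for the T cell list. For the myeloid list camera with the preset correlation gave 0.0015.

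The deposited calls are the authors' own, and a limma test of the recovered reads without pairing called 0 of 16774 genes at an adjusted p of 0.05, with 2808 at an unadjusted p under 0.05, and 46 genes without the shallower control library, where the lone control is assumed to vary like the Brg1-deleted libraries. With libraries matched across genotype by their similarity, a matching read from the data and not from the labels, limma called 2918, among them 243 of the 244 resolved deposited calls. The other matching gave 0. Choosing the matching by similarity lowers the residual spread, so the return of the deposited calls is no independent check. Across the 33 lists, 17 lay outside the central 95% of random lists, where 1.65 are expected of lists drawn at random. Members of a fixed list may vary together between libraries for any cause, so this excess is not a test of Brg1 deletion. Camera with an estimated correlation called 0 of 33, with 0 at an unadjusted p under 0.05, and with a preset correlation 15. The estimate rests on only 4 libraries, so this lack of calls cannot show that the lists did not shift.

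Knockdown of Brg1 in Rag1-null pro-B cells changed 43 genes in the authors' deposited table, 35 higher and 8 lower. The largest rises among called genes above the median level were in the nerve growth factor receptor gene Ngfr, from an authors' mean of 9.88 to 94.2, in Ncf1, a subunit of the phagocyte NADPH oxidase (chromosome 5, 134220053 to 134229625), from 63.7 to 531, in the profilin gene Pfn2, from 28.3 to 203, and in Ahnak, from 185 to 1205. Rises in Zfp385a, 4.86-fold, Lrrc32, 4.41-fold, Syndig1l, 3.95-fold, Pdlim2, 3.85-fold, Ceacam1, 3.45-fold, and Pgap1, 3.31-fold, followed in the authors' deposited table. Besides Smarca4, the falls under the same rule were in Tspan2, 2.94-fold, Crhbp, 2.93-fold, Tnfrsf19, 2.79-fold, the receptor kinase gene Epha2, 2.66-fold, Ubash3a, 2.51-fold, and Gfra1, 2.22-fold, in the authors' deposited table.

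In the fixed lists, called genes of the knockdown were Smarca4 itself and, among mature B and plasma cell markers, Ms4a1, which encodes CD20, and Cd55. When adjusted over the list alone, 3 of these markers passed, all higher. Ms4a1 went from an authors' mean of 853 to 2351 with an adjusted p of 0.0016 in the authors' deposited table. Of the lists of growth, biosynthesis, cell division and the unfolded protein response, 7 lay below the random range without a single call, while cytosolic ribosomal proteins, cholesterol synthesis, the Myc family and G2/M and mitosis lay inside it. The medians of the 7 were -0.42 for ribosome biogenesis, -0.39 for translation factors and tRNA synthetases, -0.67 for glycolysis, -0.23 for oxidative phosphorylation, -0.34 for nucleotide and one-carbon synthesis, -0.22 for G1/S and -0.38 for the unfolded protein response. In the glycolysis list 7 falls passed when adjusted over the list alone, and 0 did in each of the 6 others. Above the random range were B cell signalling, at 0.21, B lineage transcription factors, at 0.15, CDK inhibitors and cell cycle exit, at 0.34, p53 targets, at 0.22, NF-kB targets, at 0.33, MHC class II and antigen presentation, at 0.21, and SWI/SNF subunits, at 0.10. Against random lists not matched on level, only NF-kB targets and CDK inhibitors of these stayed above the range. When adjusted over the list alone, 1 SWI/SNF subunit passed, Smarca4, and none in the 6 other lists. Of 33 lists, 14 lay outside the central 95% of random lists. The myeloid list, at a median of 0.05, was inside the random range, with 0 genes adjusted over the list alone. Only 2 of its 24 listed genes had at least 10 CPM on knockdown, against 13 on deletion. Its median therefore cannot show whether the fall seen on deletion was present or absent here. Values per library could not be resolved for this experiment, whose means pool 3 libraries, and 1 control library held about 5201372 reads.

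The experiments were then compared gene by gene. Genes called in both numbered 8, all with the same direction in each. Pfn2, Tldc1, Pdlim2, Gfra2 and Pear1 were higher, and Crhbp, Smarca4 and the predicted gene Gm5537, named after its values were seen, were lower in the authors' deposited table of each experiment. Crhbp fell 12.5-fold on deletion and 2.93-fold on knockdown, and Gfra2, a receptor chain for neurturin, rose 4.42-fold and 3.06-fold, as the authors' deposited tables give them. Smarca4 is lower by design in both experiments and was left out of the tests, a choice made after the data were examined. For calls in the same direction, 5 higher genes were shared where 0.277 are expected of independent lists, with a Fisher's exact p of 7.69e-06, and 2 lower genes where 0.0561 are expected, with a Fisher's exact p of 0.0013. Fisher's exact two-sided test of the directions of these 7 genes gave p = 0.0476. The experiments share no library, and genes are not independent replicates.

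Of 285 genes called on deletion and listed in both tables, 276 had the same sign on knockdown, 96.8%. All 43 genes called on knockdown had the same sign on deletion. Both sets of calls hold Smarca4, which is lower by design. Over all 17846 shared genes, called or not, the share with the same sign was 71.9%. It was 81.7% in the 9456 genes above the median level in both tables. Across 17846 shared genes the log2 fold changes had a Pearson r of 0.35 and a Spearman rho of 0.45, and across the 9456 genes above the median level in both tables the values were 0.78 and 0.80. All of the lists outside the random range in both experiments, 12 of 33, had the same sign in each. In the genes called on deletion, the median size of the log2 fold change was 1.62 on deletion and 0.68 on knockdown, and in the genes called on knockdown it was 1.82 and 1.55. Choosing genes by their call raises the size in the experiment that made the call, and over all shared genes the medians were 0.46 and 0.28. The difference in effect between the experiments was not tested, since it would need values per library from both tables, and the tables were normalized separately.

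**Figure D2:**
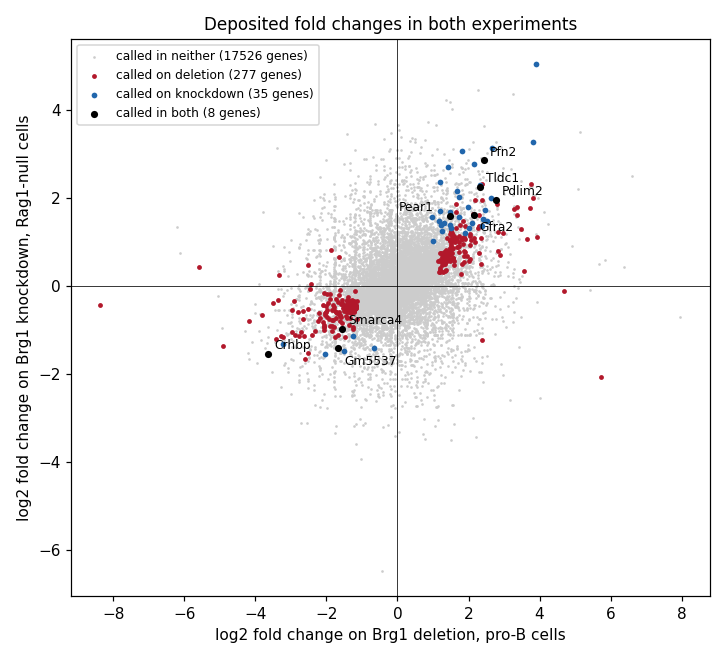
Deposited log2 fold change on Brg1 deletion in cultured pro-B cells (x axis) against that on Brg1 knockdown in Rag1-null pro-B cells (y axis), 1 point per gene of 17846 listed in both tables. Red marks genes called on deletion, blue on knockdown and black in both, and the 8 black points lie in the quadrants where both changes have the same sign.

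**Figure D3:**
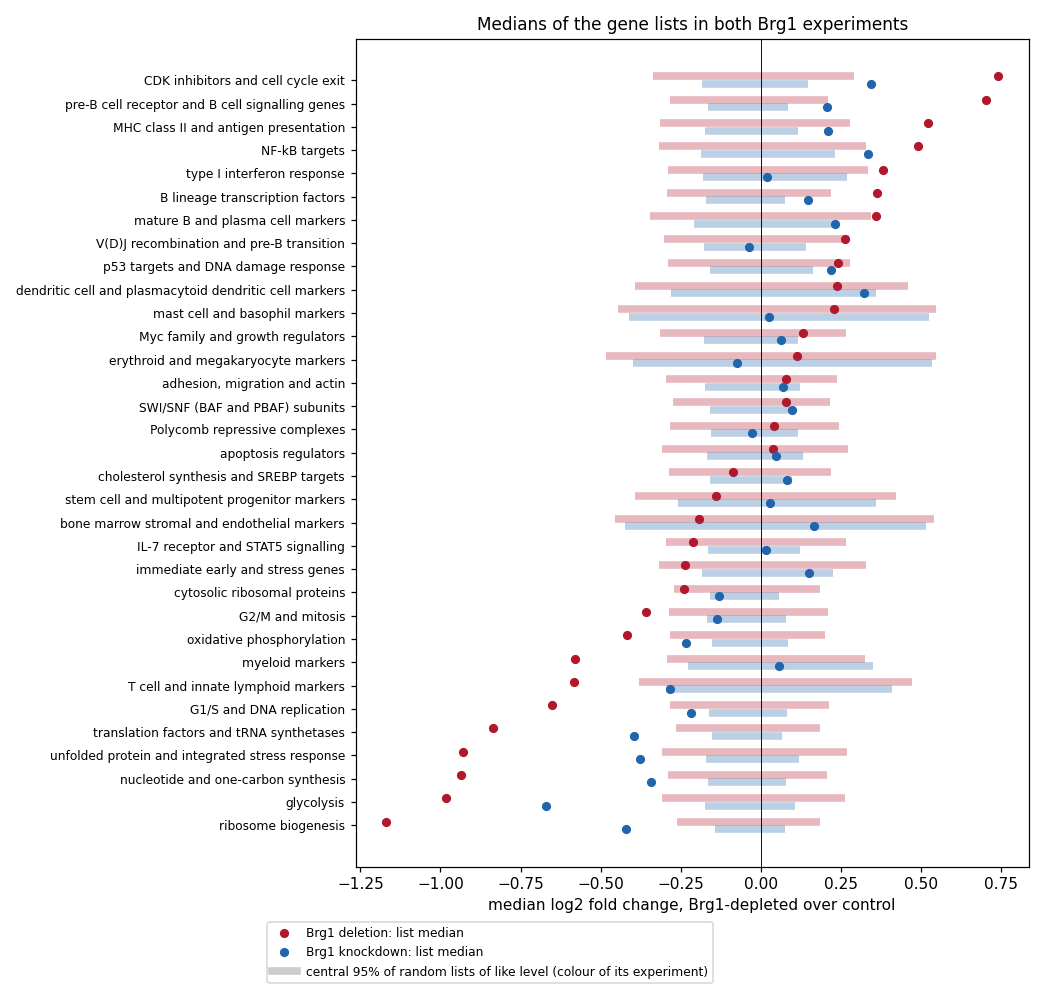
Median log2 fold change of each of the 33 gene lists on Brg1 deletion (red) and on Brg1 knockdown (blue), with bars for the central 95% of 10000 random lists of like level. Ribosome biogenesis lies lowest on deletion, at -1.17, and glycolysis lowest on knockdown, at -0.67, while CDK inhibitors and cell cycle exit lie highest in both, at 0.74 and 0.34.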

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

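Chosen after the data were examined were tests on recovered reads, the adjusted p of 0.1, the adjustment over listed genes, protein-coding genes, genes without the confounded mark, the 10 CPM minimum for correlations and lists, unmatched random lists, 1 added to the means and leaving out Smarca4. Deletion calls numbered 286 with a 1.5-fold minimum and 349 with a mean of at least 10 CPM, where the adjustment was redone over the genes left. They numbered 419 at an adjusted p of 0.1, 330 when adjusted over listed genes and 263 among protein-coding genes. The same settings gave 43, 40, 52, 49 and 40 calls on knockdown. Of the deposited calls, 233 on deletion and 32 on knockdown had a mean of at least 10 CPM. Without genes marked as confounded, 162 and 28 calls were left, as fewer genes enter. With the labels' replicate numbers, no paired analysis was possible because the deposited columns hold one mean per group and carry no replicate number. For deletion, a pairing by those numbers would be either the matching by similarity or the other matching below, and which of them is unknown. On recovered reads, limma called 0 genes without pairing, at a lowest adjusted p of 0.127, and with 1 library left out in turn between 0 and 46, the latter without the shallower control library. A lone library left in a group is there assumed to vary like the other group, so this is no measure of stability. With libraries matched across genotype by their similarity it called 2918, among them 243 of the 244 resolved deposited calls, and with the most balanced read solutions 3058. The other matching gave 0. The recovered libraries have no numbers in the labels, so this matching is read from the data and not from the design. The cause of the difference between the deposited calls and limma without pairing was not tested.

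The Spearman correlation between the experiments was 0.45 over all shared genes, 0.53 in protein-coding genes, 0.80 above the median level in both tables, 0.81 with at least 10 CPM in both and 0.81 in genes called in either. The cause was not tested. Of the 33 lists, 17 stood apart on deletion, 16 against unmatched random lists and 17 with at least 10 CPM. On knockdown these counts were 14, 11 and 17. With camera on deletion, 15 were called with a preset correlation, 16 with matched libraries, and 0 in either case with an estimated correlation. Under the 10 CPM minimum 51 of 60 list medians kept their side of the random range and their sign. Smarca4 stayed at -1.56 on deletion and at -0.98 on knockdown when all genes were centred on their median.

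Count models with other scalings, voom, fry and the smaller pseudocount were not run, and neither were leave-one-out fits of the deposited calls. All 284 values of named genes kept their sign with 1 added to the means. The rounding of p-values and the genes that are adjusted for but not listed limit every adjustment made here.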

Other observations

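The tests of depth, shared preparation, scaling, cell division and the floxed allele were chosen only after the results they bear on were seen, while those of sex, of other cell types and of single pairs were set before their results. Lists of immune response genes lay above the random range after Brg1 deletion with few single calls. MHC class II and antigen presentation had a median log2 fold change of 0.52, with 18 of 19 genes above 0 and none called. Some members of this list differed widely between libraries of 1 group. H2-Aa, chosen like H2-Eb1 after its values were seen, stood at 89.7 and 973 normalized reads in the 2 control libraries and at 96.5 and 1220 in the 2 Brg1-deleted libraries, and H2-Eb1 at 48.8 and 715 in controls and at 91.9 and 1058 after deletion. Both were higher in the libraries where the macrophage gene C1qb was higher. NF-kB targets had a median of 0.49 with 15 of 20 above 0 and none called. Type I interferon response genes had a median of 0.38 with 1 called rise of 25, in the RNA sensor gene Ddx58, 2.31-fold in the authors' deposited table. On knockdown their median was 0.02, and 0.205 in genes with at least 10 CPM, both inside the random range. On deletion the interferon median was 1.00 in 1 matched pair of libraries, 0.25 in the other and 0.78 in genes with at least 10 CPM. Mature B and plasma cell markers had medians of 0.36 on deletion and 0.23 on knockdown. The former was 0.16 and 0.27 for resolved members in the matched pairs, lay inside the range of random lists not matched on level and, at 0.31, inside it in genes with at least 10 CPM, where the latter, at 0.22, lay above it. Adjusted over the list alone, 0 genes passed for MHC class II and NF-kB on deletion, 1 for interferon, higher, and 1 for mature B markers, lower. In camera the adjusted p of these lists, in the same order, was 0.845, 0.726, 0.845 and 0.870 with an estimated correlation. With the preset correlation it was 0.0751, 0.0156, 0.0156 and 0.310.

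Several lists lay inside the random range on deletion when all listed genes were used. In genes with at least 10 CPM the p53 median was 0.39 and above the range. Camera gave an adjusted p = 0.726 for this list with an estimated correlation and 0.0156 with the preset one. The same minimum turned the sign of the immediate early median, to 0.26, of Polycomb, to -0.09, of stem cell markers, to 0.07, and of the Myc family, to -0.04, all inside the range. Over all listed genes, the p53 list had a median of 0.24 with a called rise in Plk2, 4.50-fold in the authors' deposited table, the apoptosis list 0.04 with one in the initiator caspase gene Casp9, 2.79-fold in the authors' deposited table, the immediate early list -0.24 with one in the mRNA decay factor gene Zfp36, and the adhesion list 0.08 with one in Icam2. Medians were 0.08 for SWI/SNF subunits, where Smarca4 alone was called, -0.21 for IL-7 receptor and STAT5 signalling, -0.09 for cholesterol synthesis, 0.04 for Polycomb, -0.14 for stem cell markers, 0.24 for dendritic cells, where Irf8 was called higher and Ly6c2 lower, 0.23 for mast cells, 0.11 for erythroid cells and -0.19 for stromal cells. Adjusted over the list alone, 4 genes passed in the p53 list, 3 each among SWI/SNF subunits and dendritic cell markers and 2 each in the apoptosis, immediate early and Polycomb lists. In the adhesion and stromal lists 1 each passed, and 0 in the IL-7, cholesterol, stem cell, mast cell and erythroid lists. For SWI/SNF subunits and the immediate early, adhesion and mast cell lists, camera without matching gave a direction opposite in sign to the median. On knockdown, inside the random range, medians were -0.13 for ribosomal proteins, -0.14 for G2/M, -0.04 for V(D)J recombination, 0.06 for the Myc family, 0.02 for IL-7 signalling, 0.08 for cholesterol synthesis, 0.05 for apoptosis, 0.15 for immediate early genes, 0.07 for adhesion, -0.03 for Polycomb, 0.03 for stem cells, -0.28 for T cells, 0.32 for dendritic cells, 0.02 for mast cells, -0.07 for erythroid cells and 0.16 for stromal cells, with 2 genes passing in the IL-7 list and 1 each in the stem cell, T cell and mast cell lists when adjusted over the list alone. The T cell list, at -0.32, lay below and the dendritic cell list, at 0.37, above the range in genes with at least 10 CPM.

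The 4 recovered libraries of the deletion experiment can be matched across genotype in 2 ways, whose correlations of deviations from the group means are equal in size and opposite in sign by construction, so only the size, 0.63 over 11821 genes, and which libraries the positive matching joins are informative. It joins the deeper library of each group with the shallower of the other. A depth effect needs a positive value between libraries of like depth order, which had -0.63. The control libraries differed little in depth, with size factors of 1.03 and 0.999, so this cannot exclude a depth effect. Sex of the donor mice would act mainly through X and Y, and the correlation was 0.63 on autosomes. The Y-linked gene Ddx3y stood at 859 and 994 in 1 pair and at 565 and 833 in the other. Every library thus held cells of male mice, though the share of such cells may differ. Other cell types as the whole cause would dilute B lineage genes alike if only B cells express them. The deviations of these genes correlated between matched libraries, at 0.76 over 16 genes with a one-sided permutation p of 4.0e-05. The positive matching was chosen on genes that include these, and the permutation takes genes as independent. This p is therefore no test over libraries. The premise of an equal dilution was not tested either, so other cell types are not excluded. The pairs did differ in the macrophage gene C1qb, at 11.7 and 9.30 in 1 pair and 210 and 117 in the other. The libraries of a pair differ in their Brg1 alleles and so cannot come from 1 culture. A shared day or batch of culture or preparation may account for the pairs, and stays open because the labels give no batch.

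Several growth and biosynthesis lists, but not cytosolic ribosomal proteins, cholesterol synthesis or the Myc family, lay below the random range after deletion while B cell signalling lay above it, at a median of 0.70, which scaling of whole libraries cannot give. For ribosome biogenesis and B cell signalling the adjusted p was 0.726 with an estimated correlation. Camera with the preset correlation gave 4.67e-14 and 0.0172. The fall in ribosome biogenesis was present in both matched pairs, and the weaker of them had a median of -1.01. Fewer dividing cells as the whole cause were assumed to lower G2/M genes at least as far, which was not tested. The ribosome biogenesis median was lower than that of G2/M by a difference of -0.81, with a 95% bootstrap interval over genes from -0.91 to -0.69. For resolved members the difference was -0.95 and -0.40 in the matched pairs, so the interval over genes leaves out the spread between libraries. Only under that assumption do these values speak against fewer dividing cells as the whole cause. Brg1 loss itself, which the design names, and a shift towards later B cell stages were not tested as explanations and stay open.

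Col5a3 lies 0.801 Mb from Smarca4 and was nearly absent after deletion, at 0 and 2.33 normalized reads in the 2 libraries. On knockdown it had authors' means of 48.4 and 35.5 and an adjusted p of 1 in the authors' deposited table. A strain segment carried with the floxed allele may be the source, but within 5 Mb of Smarca4 2 of 97 other genes were called, Col5a3 and, named after its value was seen, AB124611, with a one-sided Fisher's exact p of 0.418. This cannot be told apart from an effect of Brg1 loss, as the allele and the genotype come together and the knockdown leaves part of Brg1.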
